A study of Mus musculus with 76 samples.

How the data were processed

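RNA was measured in 76 single mouse cells called iHPCs, which the labels describe as progenitors obtained from pluripotent stem cells carrying inducible Runx1, Hoxa9 and Hoxa10. Per the labels' protocols, single cells were sorted, cDNA was amplified with the Discover-sc WTA Kit V2 and libraries were made with the TruePrep DNA Library Prep Kit V2 (both Vazyme). Every cell belonged to 1 group. No culture, animal or sort was named for any cell, so the group counted as 1 sample, and no p-value or standard error was made from cells. Each title carried a letter from A to H and a number from 2 to 11, which has the form of a plate position, although the labels do not say so.

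The authors deposited 1 table of TPM, the share of transcripts after scaling for gene length, with 15192 genes and a column for each cell. Every column summed to 1000000 over the genes it listed, so library depth was not kept and is unknown. Per the submitters' processing notes, bcl2fastq, HISAT2 2.1.0, SAMtools 0.1.19, StringTie 1.3.4 and the build mm10 were used; the order of steps, the annotation and any gene filter are not given in the sources used here. No mitochondrial gene was listed. Of the genes, 2391 were at 0 in every cell, and 66.3% of all values were 0. An exact 0 in TPM can be a failed capture: Polr2a reached 1 TPM in 22 cells and Tbp in 36, although every cell uses them. Gene-level TPM does not separate transcripts of introduced copies from those of the chromosomal genes. Of the listed symbols, 92.3% were symbols in the RefSeq annotation of GRCm38.p6, and 4 list genes were found under an older symbol.

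The following choices were made before the data were examined. A gene counted as detected in a cell at 1 TPM or more. Shares of cells carry exact Clopper-Pearson 95% intervals; for 0 of 76 cells, 3 counts give an upper limit of 3.95%. Intervals and limits cover the counting of cells only. The 27 gene lists held 359 genes, of which 301 were listed in the table. Co-detection of lineages required at least 2 members of each list, with the early, B and T lymphoid lists taken as 1. Coherence of a list was its mean pairwise Spearman correlation (rho) across cells of log2(TPM + 1), for lists with at least 4 members detected in at least 5 cells. It was placed among 10000 random lists of the same size matched on mean level and on cells detected; the percentile describes these cells and is not a test. Cells were clustered on the 1000 most variable genes, leaving out ribosomal-protein genes and every list gene, with 10 principal components and Ward linkage. The number of clusters, from 2 to 6, was the one with the highest mean silhouette. No doublet caller was run, since per the labels each library was made from a sorted single cell. Settled later, during the computation, was that each random member was drawn from the 100 genes nearest in level and detection, so that a gene can recur within a random list.

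Genes named in the text followed a rule fixed in advance. It took the 3 introduced factors, the 4 members of each list detected in most cells (2 for some lists), and the 10 genes with the highest mean level outside ribosomal-protein genes. It added the 10 most variable genes among those in 20 to 80% of cells, and the 10 genes that differed most for each cluster. Further genes were chosen after their values were seen: Polr2a, Tbp, Gata2, Meis1, Hlf, Mecom, Kit, Flt3, Irf8, Elane, S100a8, S100a9, Col1a1, Hba-a1, Cd3d, Cd3e, Bcl11b, Plscr1, Skap2, Hbb-b1, Hbb-b2, Gm5506, Fos, Lat, Cd5 and Cbx3. Some genes taken by the rule or by this choice are not reported here. The correlations between pairs of genes and between pairs of lists were also chosen after values were seen.

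Other settings chosen in advance were detection at any value above 0 or at 5 TPM, cells with at least 2000 genes, and title numbers 2 to 6 or 7 to 11. For co-detection they were at least 1 or 3 members. For coherence they were a pseudocount of 0.1, Pearson correlation, regression on genes detected, a minimum of 10 cells and rescaling without ribosomal-protein genes. For clusters they were 500 or 2000 variable genes, a pseudocount of 0.1, k-means, 5 components and regression on genes detected. A threshold of 10 TPM, values under 10 TPM set to 0, cells with at least 3500 genes, co-detection without members found in over 90% of cells, and coherence without the cells of cluster 4 were added after seeing the data. Alternatives used 2000 random lists. Without a test, a share was taken to have moved when it left the 95% interval, a count when it changed by over 1.5 times and a rho when it changed by more than the SD of its matched random lists.

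The procedures were tested on simulated data made by shuffling each gene over cells. Of 40 unrelated lists of 15 genes, 1 lay above the central 95% of matched lists, and all 40 such lists given a shared component did. Of 40 lists of 5 genes, 37 did so with a weaker and 40 with a stronger shared component. Of 100 unrelated pairs of lists, 5 lay above and 1 below the central 95%. The genes within each of these lists were also unrelated, so lists whose members vary together were not covered. For clusters, 1 table was made per group size, and the planted cells were given the highest values of every changed gene. Recovery of groups with a weaker separation was not covered. A planted group of 6 cells with 200 changed genes was recovered whole. Of a planted group of 12 cells, 9 fell in 1 cluster and the others were split off, so cluster boundaries are approximate. An earlier form of that group, in which the planted values formed a gradient over its cells, was not recovered as a group, and the simulation was then changed to permute them. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9.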

Results

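The transcriptomes of 76 single iHPCs were examined to describe which regulators, surface molecules and lineage genes progenitors made from pluripotent stem cells with Runx1, Hoxa9 and Hoxa10 carry. A median of 4182.5 genes per cell reached 1 TPM (range 2465 to 5992, SD 678), and 505 genes did so in every cell. The 10 most abundant genes took a median of 7.17% of a cell's TPM and ribosomal-protein genes 7.71%. Cells with title numbers 10 and 11 had medians of 3638 and 3792 genes, against 4096.5 to 4469.5 for the other numbers. Correlations between pairs of cells ran from 0.476 to 0.766, so no cell appeared in the table under more than 1 title. The highest mean levels outside ribosomal-protein genes belonged to Ifitm1 (median 11315 TPM), Ftl1 (8616 TPM), Ubb (7531 TPM), Actb (6183 TPM) and Eno1 (5677 TPM). The value of Eno1 is uncertain, since its near-identical copy Gm5506 had a median of 3700.0 TPM and reads of both can be exchanged.

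Of the 3 introduced transcription factors, Runx1, a regulator of blood cell emergence (chromosome 16, 92601466 to 92826074, GRCm38.p6), was detected in 73 of 76 cells (96.1%, interval 88.9 to 99.2%), with a median of 100.4 TPM and an interquartile range of 56.1 to 154 TPM. Hoxa10 (chromosome 6, 52231197 to 52240854) was detected in 28 cells (36.8%, 26.1 to 48.7%) and Hoxa9 (chromosome 6, 52223097 to 52227370) in 18 cells (23.7%, 14.7 to 34.8%). All 3 were detected in 16 cells, Runx1 without either Hox gene in 43, and none in 3. Hoxa9 and Hoxa10 were found together in 16 cells, where independent shares would give 6.63. Across cells, Runx1 correlated with Hoxa10 (rho 0.63, Pearson r 0.46) and with Hoxa9 (rho 0.49, r 0.39), and Hoxa9 with Hoxa10 (rho 0.55, r 0.55). Each rho lay above the central 95% of 10000 pairs of genes matched on level and detection, which ended at 0.24, 0.24 and 0.25 for the 3 pairs in the order Runx1 with Hoxa9, Runx1 with Hoxa10 and Hoxa9 with Hoxa10. Within title numbers 2 to 6 (37 cells) the rho of Runx1 with Hoxa9 was 0.28 and within numbers 7 to 11 (39 cells) it was 0.60. With Hoxa10 the values were 0.52 and 0.66. No matched range was computed for these smaller sets of cells, where random values spread more widely. The 0.28 can thus not be told from matched pairs. Without the 2 cells farthest from the median of Runx1, the rho with Runx1 was 0.48 for Hoxa9 and 0.62 for Hoxa10. At 10 TPM, Hoxa9 remained in 14.5% and Hoxa10 in 23.7% of cells, and Hoxa9 with Hoxa10 in 9 cells against 2.61 from independent shares.

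**Figure D1:**
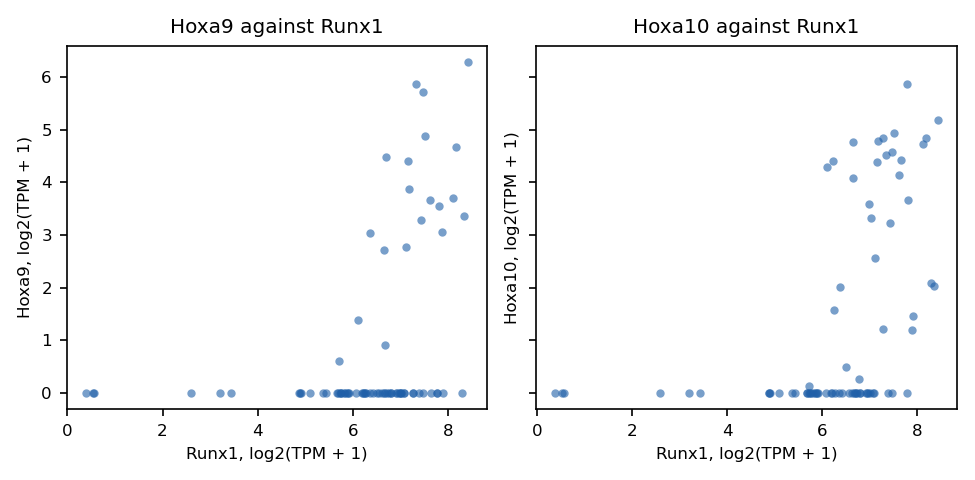
Level of Hoxa9 (left) and Hoxa10 (right) against Runx1 in each of 76 cells, all as log2(TPM + 1); each point is a cell. Most cells lie at 0 for the Hox genes, and the rho with Runx1 was 0.49 for Hoxa9 and 0.63 for Hoxa10.

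Genes common to blood cells were found nearly throughout. All 12 pan-haematopoietic genes were detected in at least 50% of cells, with a median of 12 per cell, and Arhgdib (median 3684 TPM), Coro1a (1293 TPM), Lsp1 (1196 TPM) and Gmfg (727 TPM) were in every cell. Among surface molecules of stem and progenitor cells, Cd48 (median 900 TPM) and Cd34 (666 TPM) were in all 76 cells, Ly6a (Sca-1) in 65, Adgrg1 in 64, Kit in 43 and Flt3 in 40; a median of 8 of 18 was detected per cell. Among transcriptional regulators of these cells, Lyl1 was in 67, Lmo2 in 58, Fli1 in 53, Msi2 in 44 (27 at 10 TPM), Gata2 in 36, Meis1 in 21 and Hlf in 8 cells, and Mecom in 0 of 76, which allows a share of up to 3.95% by 3 counts (4.74% by the exact interval); a median of 5 of 19 listed regulators was detected per cell. Of the 17 other HoxA and HoxB genes, only 2, Hoxa3 and Hoxb4, were listed, and both were detected in 0 cells. The unlisted ones cannot be called absent.

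Genes of several mature lineages were present as well. Counts at 10 TPM are given beside genes of this and the next 2 paragraphs that fell by over 1.5 times and beside some others, because low values of genes high in 1 cell were found in 7.51% of cells sharing the letter of its title and 5.76% sharing the number, against 1.52% of the others. Of the granulocyte-monocyte list, a median of 7 of 22 members was detected per cell, and 3 members were in 0 cells. Its neutrophil granule protease genes Prtn3 and Ctsg and the myeloperoxidase gene Mpo were in 67, 56 and 58 cells. At 10 TPM these fell to 55, 28 and 38 cells. A further granule protease gene, Elane, was in 2 cells. The Fc receptor gene Fcgr3 was in 69 and the regulator Irf8 in 44. The late neutrophil genes S100a8 and S100a9 were in 0 cells. Calr, a chaperone gene in the same list, was in all 76 cells. Adgre1 (F4/80) of the macrophage list was in 60 cells, Cd68 in 25, and Apoe and Maf in 14 each (7 and 1 at 10 TPM). The mast cell protease gene Cpa3 was in 75 cells (54 at 10 TPM), whereas Tpsb2 and Cma1 reached 1 TPM in 25 and 12 cells and 10 TPM in 0. Cpa3 reached 23326 TPM in its highest cell. Only values under 10 TPM were examined for following a title. Counts at 10 TPM of Cpa3 and other genes with very high cells may therefore still hold such values. Of the dendritic list, Cd74 was in 64 (20 at 10 TPM), Bst2 in 63, H2-Ab1 in 62 (38 at 10 TPM) and Tcf4 in 60 cells.

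Of the early lymphoid list, Ikzf1 was in 45 cells, Bcl11a in 42 and Satb1 in 30. Of the T lymphoid list, the kinase gene Lck was in 44 cells and the transcription factor genes Tcf7 and Gata3 in 37 and 27; at 10 TPM these were 30, 15 and 19 cells. Cd3g was in 9 cells and Bcl11b in 0. Of the B lymphoid list, Cd79b was in 28 cells, Vpreb1 and Igll1 in 1 each, and Cd79a in 0. Only 6 of its 11 genes were listed. Ebf1, Pax5, Ighm, Blnk and Ms4a1 were not, so their absence from the cells cannot be inferred. Of the NK and innate lymphoid list, Nkg7 and Id2 were in 73 cells each and Gzma in 22, falling to 47, 45 and 6 cells at 10 TPM. The genes named are mostly the members found in most cells. Over whole lists, the median per cell was 1 of 12 macrophage, 2 of 11 mast cell, 4 of 12 dendritic, 3 of 11 early lymphoid, 1.5 of 10 T lymphoid, 0 of 6 B lymphoid and 2 of 9 NK genes, and 5, 3, 2, 0, 2, 3 and 4 members of the lists in this order were in 0 cells. At 10 TPM the medians in the same order were 1, 1, 3, 2, 1, 0 and 1.

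Of the erythroid list, the beta-globin gene Hbb-bs was in 75 cells with a median of 895 TPM and Car2 in 59, but the alpha-globin gene Hba-a2 was in 5 (3 at 10 TPM) and Klf1 in 1. Hbb-bs, Hbb-b1 and Hbb-b2 are near-identical, so the split of reads between them is uncertain. Nfe2 of the megakaryocyte list was in 75 cells, Itgb3 in 16, Zfpm1 in 9 and Pf4 in 2. Of the endothelial list, Egfl7 was in 73, Eng in 37, Pecam1 in 24 and Plvap in 18 cells. The median per cell was 2 of 10 erythroid, 1 of 11 megakaryocyte and 2 of 10 endothelial genes, and 5, 4 and 3 members were in 0 cells. Pou5f1 of the pluripotency list and Eomes and Tbx6 of the early mesoderm list were in 0 cells, and Dppa5a in 1. Only 5 of 14 pluripotency and 3 of 8 early mesoderm genes were listed, so the others cannot be called absent. The same holds for the erythroid list, with 10 of 16 genes listed, and the endothelial list, with 10 of 18. Of the stromal fibroblast list, Pdgfrb was in 22 (12 at 10 TPM) and Sparc in 2 cells, and Col1a1 in 0.

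**Figure D2:**
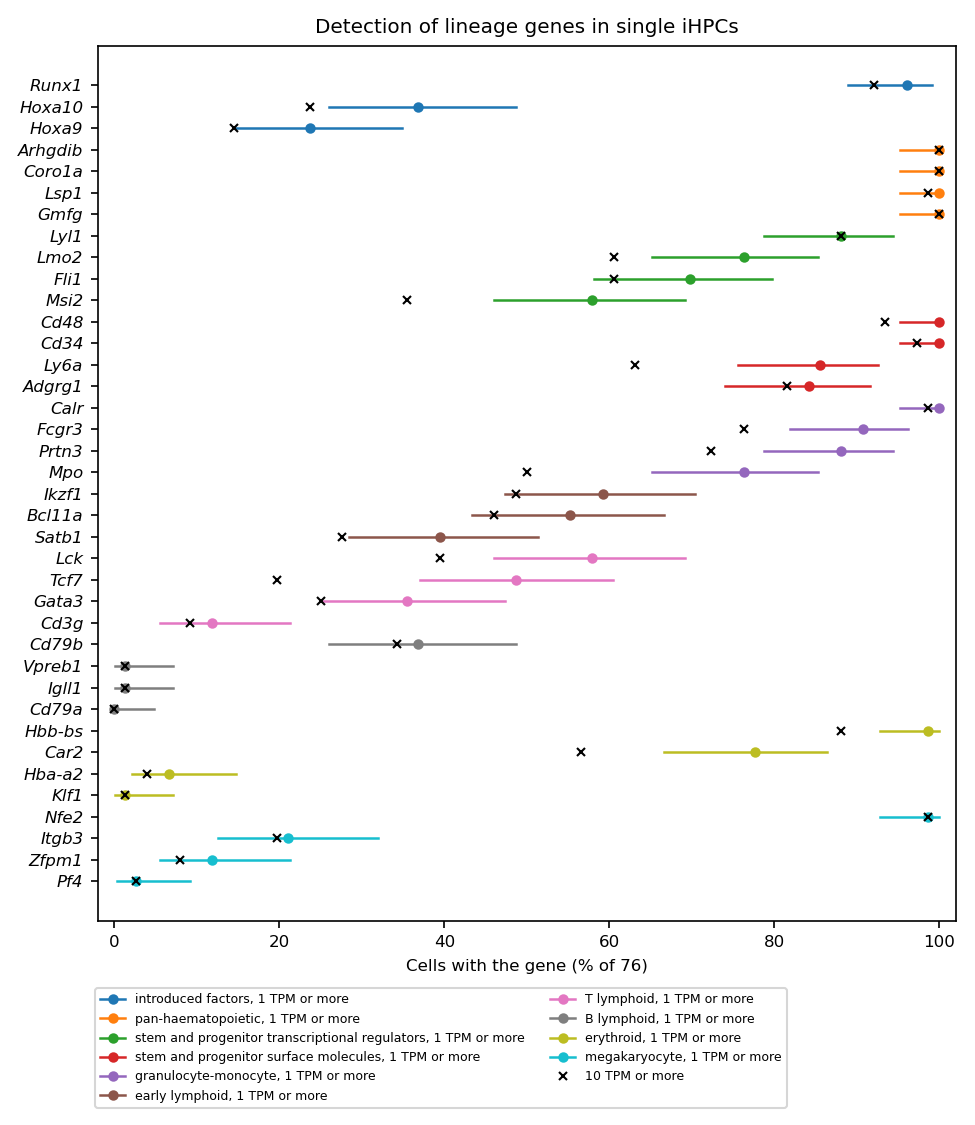
Percent of 76 cells in which each gene was detected, by gene list. Filled circles give the share at 1 TPM with its 95% Clopper-Pearson interval and crosses the share at 10 TPM; Runx1 stands at 96.1%, Tcf7 falls from 48.7% to 19.7%, and Cd79a is at 0.

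Detection of 2 members of each of 2 lineages in the same cell was frequent. At least 2 granulocyte-monocyte genes were found in all 76 cells and at least 2 lymphoid genes in 73, so both were in 73 cells (96.1%, interval 88.9 to 99.2%). Granulocyte-monocyte with erythroid genes were in 59 cells (77.6%, 66.6 to 86.4%) and granulocyte-monocyte with megakaryocyte genes in 26 (34.2%, 23.7 to 45.99%). Lymphoid with erythroid genes were in 56 cells against 56.7 from independent shares, and erythroid with megakaryocyte genes in 20 against 20.2. Calr, Fcgr3, Hbb-bs and Nfe2 were each in over 90% of cells. Without members in over 90% of cells, granulocyte-monocyte with lymphoid genes were in 85.5% of cells (65 cells against 64.4 from independent shares). With erythroid genes the share was 9.21% and with megakaryocyte genes 9.21%. With at least 3 members, the shares were 88.2%, 7.89% and 9.21%, so most cells of the erythroid and megakaryocyte pairs had only 2 members of that list. The frequent erythroid members were Hbb-bs (75 cells) and Car2 (59). Of the megakaryocyte list only Nfe2 (75) was frequent, and the next member, Itgb3, was in 16. At 10 TPM, Tcf7 was found with Lck in 15 of its 15 cells, where independent shares would give 5.92, and with Ctsg in 1 cell against 5.53. Other pairs lay closer to their expectation: Mpo with Tcf7 in 5 cells against 7.5, Mpo with Lck in 15 against 15 and Prtn3 with Lck in 20 against 21.7, while Ctsg with Lck was in 5 against 11.1.

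Cells differed in cell cycle genes, which varied together most. A median of 11.5 of 23 S phase genes (range 4 to 23) and 4 of 22 G2 and M phase genes (range 0 to 21) was detected per cell, and the cell cycle inhibitor gene Cdkn1a was in 61 cells. The most variable genes found in 20 to 80% of cells included Tsc22d1, Car2, Ctsg, Ms4a3, Mpo and Birc5. The 23 S phase genes, among them Pcna, Mcm6, Fen1 and Slbp, had a mean rho of 0.41 and the 22 G2 and M phase genes, among them Cenpa, Cdk1, Ccnb2 and Cdc20, 0.34; both lay above all 10000 matched random lists. The 5 T lymphoid genes tested (rho 0.24), the 13 glycolysis genes (0.23), the 14 granulocyte-monocyte genes (0.098) and the 7 interferon response genes (0.10) also lay above the central 95% of their random lists, as did the pan-haematopoietic genes (0.076, percentile 98.2). Stem and progenitor surface molecules (0.031, percentile 92.3) and transcriptional regulators (0.014, percentile 50.04) lay within the range of random lists, as did the early lymphoid (0.053, percentile 95.9), dendritic, mast cell, macrophage, endothelial, quiescence, stress and housekeeping lists. In all, 17 lists were compared. The early lymphoid list lay above the range with Pearson correlation (rho 0.12), with genes detected regressed out (percentile 99.3) and with values under 10 TPM set to 0 (rho 0.097), the surface molecules with genes detected regressed out (percentile 99.05), and the quiescence list within title numbers 2 to 6 (rho 0.11). Within title numbers 7 to 11, the granulocyte-monocyte rho was 0.057 and the interferon rho 0.051, both inside the random range, and within numbers 2 to 6 they were 0.16 and 0.17. The pan-haematopoietic list lay inside the random range in both (percentiles 94.05 and 97.1) and with Pearson correlation (92.5), where the T lymphoid value was 0.38.

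**Figure D3:**
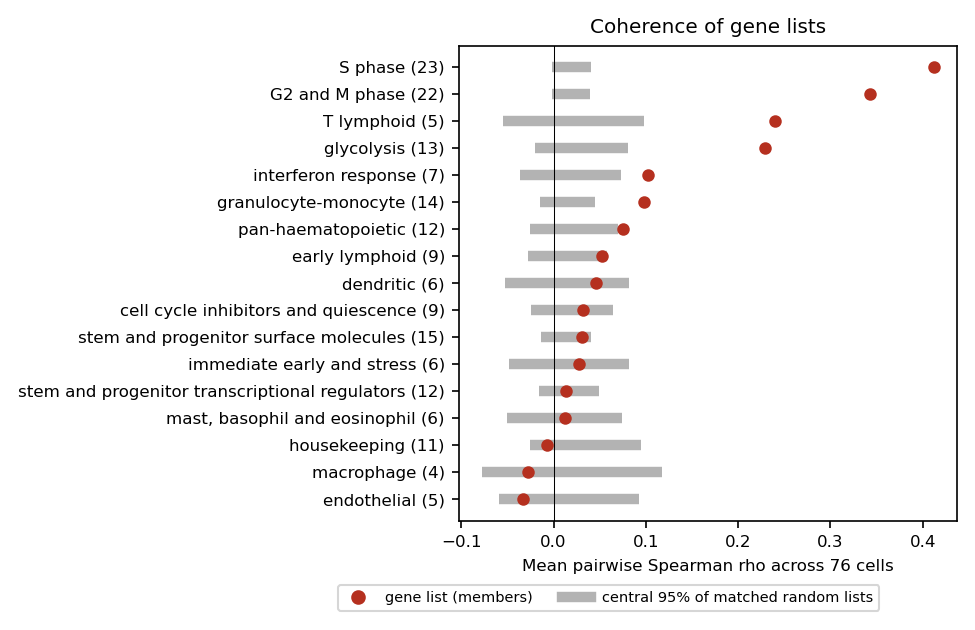
Mean pairwise Spearman rho of each gene list across 76 cells (circles), with the number of members tested in brackets and the central 95% of 10000 matched random lists (grey bars). S phase (0.41) and G2 and M phase (0.34) genes lie farthest from their bars, and the transcriptional regulators of stem and progenitor cells (0.014) lie inside theirs.

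Clustering without the list genes gave 6 clusters of 38, 12, 8, 6, 6 and 6 cells, with a mean silhouette of 0.174. The values for 2, 3, 4 and 5 clusters were close (0.143, 0.160, 0.170 and 0.163), and 6 was the highest number tried. The highest value in 20 tables with each gene shuffled was 0.10. Shuffling removes all shared variation of genes, gradual variation included, so this does not show that the clusters are separate groups. The largest cluster had a median of 4557 genes per cell against 3920 in the other cells, and Pcna, Shmt1 and Rfc5 were among its leading genes. Cluster 2 was led by Clec10a, Lmo2 and Ctla2b, cluster 3 by Vegfc, Nt5c3 and Cd59a, cluster 5 by Gpatch3, Rpp25l and Tmem203, and cluster 6 by Myadm and Gclm. None was given a cell type name. Cluster 4 was led by Trat1, Tcf7, Tmem121, Cd72 and Gzma, and Lck, Cpa3 and Tox were also among its 10 leading genes. Of these, Trat1, Tmem121 and Cd72 took part in the clustering. List genes that vary with them would follow, so values of list genes in cluster 4 are not independent support for it. Of the T lymphoid genes, which took no part in the clustering, Tcf7 (median 811 TPM) and Lck (651 TPM) were at 10 TPM or more in 6 of its 6 cells, against 9 and 24 of the 70 other cells; Gata3 was so in 2 of the 6 against 17 of the others, Cd3d and Cd3g in 3 cells of the 6 each and Cd3e in 0. Prtn3 and Ctsg reached 10 TPM in 0 of its 6 cells, against 55 and 28 of the others. It stayed unnamed because Gzma of the NK list, Cpa3 of the mast cell list and the B cell gene Cd72 were among its leading genes. The number of clusters was 2 or 3 under 5 of 7 other settings, and 3 to 5 of the 6 cells of cluster 4 shared a cluster of 3 to 9 cells under 7; with at least 3500 genes per cell the group was not recovered, its 4 remaining cells lying in a cluster of 47.

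**Figure D4:**
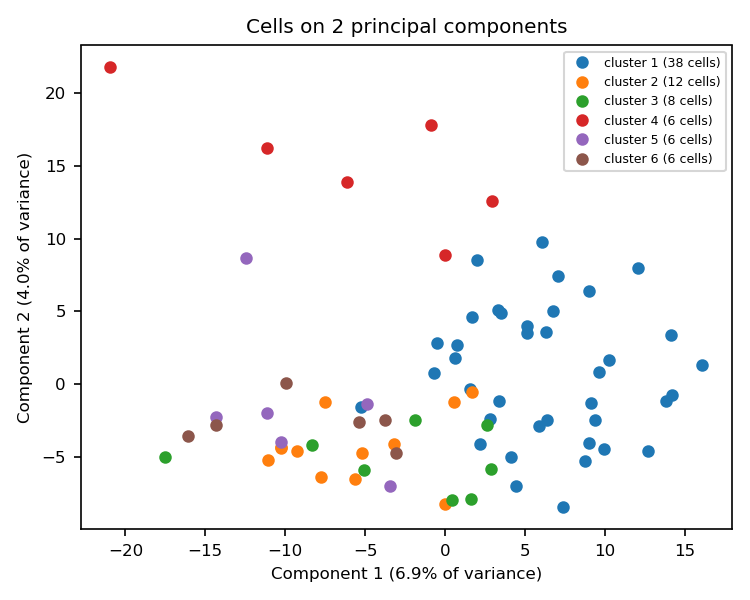
The 76 cells on the first 2 principal components of the 1000 most variable genes outside the gene lists, which held 6.9% and 4.0% of the variance. Colours mark the 6 clusters of 38, 12, 8, 6, 6 and 6 cells.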

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

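Settings named as added were chosen after seeing the data; the others were planned. The filter of at least 2000 genes removed no cell and so tested nothing. The share of cells with Runx1 was 100% at any value above 0 and within title numbers 2 to 6. At the added 10 TPM, Hoxa9 was in 14.5%, Hoxa10 in 23.7% and all 3 factors in 11.8% of cells. Granulocyte-monocyte with lymphoid genes were in 100% of cells with at least 1 member or any value above 0, in 88.2% with at least 3 members or at 5 TPM, and in 85.5% at the added 10 TPM or, also added, without members found in over 90% of cells. With erythroid genes, the share was 100% with at least 1 member, 7.89% with at least 3, 92.1% at any value above 0, 55.3% at 5 TPM, 53.9% at 10 TPM and 9.21% without the frequent members. With megakaryocyte genes it was 98.7% with at least 1 member, 9.21% with at least 3, 47.4% at any value above 0 and 9.21% without the frequent members. The granulocyte-monocyte rho was 0.12 with a pseudocount of 0.1 and Pearson correlation, 0.13 with Pearson correlation, 0.16 and 0.057 in title numbers 2 to 6 and 7 to 11, and 0.13 with values under 10 TPM set to 0 (added). The T lymphoid rho was 0.34 and 0.38 under the same 2 Pearson settings, 0.17 in numbers 7 to 11, 0.35 with low values at 0 and 0.18 without the cells of cluster 4 (added). With members in at least 10 cells and in numbers 2 to 6, too few T lymphoid members were left and the list was not tested. The S phase rho was 0.37 with genes detected regressed out, 0.32 and 0.48 in the 2 ranges of numbers, 0.44 with low values at 0, 0.43 in cells with at least 3500 genes (added) and 0.43 without cluster 4. The G2 and M phase rho was 0.42 and 0.43 with Pearson correlation at either pseudocount, 0.28 with genes detected regressed out, 0.36 with members in at least 10 cells, 0.41 in numbers 2 to 6, 0.42 with low values at 0, 0.36 with at least 3500 genes and 0.36 without cluster 4. The interferon rho was 0.14 and 0.15 with Pearson correlation, 0.17 and 0.051 in the 2 ranges of numbers and 0.16 with low values at 0; that of the stem and progenitor regulators was 0.036 in numbers 2 to 6. The pan-haematopoietic rho, at percentile 98.2 in the main setting, was at 91.5 and 92.5 with Pearson correlation, 97.1 in numbers 2 to 6 and 94.05 in numbers 7 to 11, each inside the random range. No rho of a list above the central 95% of its random lists changed sign. The number of clusters was 3 with 2000 variable genes, a pseudocount of 0.1 or 5 components, and 2 with genes detected regressed out or with at least 3500 genes. Of the 6 cells of cluster 4, 3 were found together with 500 variable genes, 4 with 2000 variable genes, a pseudocount of 0.1, k-means or 5 components, and 5 with genes detected regressed out or low values at 0; these clusters held 3 to 9 cells. With at least 3500 genes its 4 remaining cells fell in a cluster of 47. Over the settings other than the filter of at least 2000 genes, shares of other named genes stayed within their interval 479 times, rose 55 times and fell 78 times; the rho of the other lists stayed within 1 SD of its random lists 71 times, rose 12 times and fell 4 times. The cause of these changes was not tested. Depth is unknown, so absence of a gene from a cell cannot be told from failed capture.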

Other observations

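The genes and pairs in this part were chosen after their values were seen. Of 9684 genes, the highest rho with Runx1 was that of the phospholipid scramblase gene Plscr1 (0.64), followed by Hoxa10 (0.63) and the progenitor regulator Lmo2 (0.60). The 2 genes closest to Hoxa10 were Runx1 (0.63) and Hoxa9 (0.55), and the third was Skap2 (0.51), an adaptor gene within 1 Mb of Hoxa10. Among 136 pairs of gene lists, 22 mean correlations lay above and 22 below the central 95% of matched random lists. The random lists were drawn gene by gene and so lacked the internal correlation of lists such as S phase. Lists with such correlation can fall outside this range without a relation to the other list. These counts thus do not measure how many pairs of lists are related. T lymphoid genes correlated with early lymphoid genes (mean rho 0.14) and inversely with granulocyte-monocyte genes (-0.090), and S phase genes inversely with pan-haematopoietic (-0.14) and glycolysis genes (-0.11). Hbb-bs had a median of 895 TPM while Hba-a2 was in 5 cells and Hba-a1 in 0. Fos was in 32 cells at 1 TPM and in 1 at 10 TPM, while the immediate early gene Ier2 was at 10 TPM or more in 71.

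Of the tests below, those of Runx1 against genes detected and against shared indices were set down before their values were computed; the others were chosen after the result was seen. The design gives 1 group, so no biological explanation was tested by comparing groups; the HoxA region and mature T cells are weighed below as sources of transcripts.

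Low values of genes that were high in 1 cell lay in cells sharing the letter or the number of that cell's title. Over 223 genes at 10 TPM or more in exactly 1 cell, and there at 100 TPM or more, values between 0 and 10 TPM were found in 7.51% of cells with the same letter, 5.76% with the same number and 1.52% with neither. At 3 or more positions away, the share was 4.77 times that of cells sharing neither (3.21 to 8.25 over resampled genes), and the low values had a median of 0.21% of the high cell; reads assigned to the wrong library through a shared index may account for this. Diagonal neighbours had 0.89 times the share of other cells sharing neither (0.41 to 1.58), so spill between adjacent wells remains open.

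Hoxa9 and Hoxa10 followed Runx1 across the 76 cells, although within title numbers 2 to 6 the rho of Hoxa9 was only 0.28. The mean rho over both genes was 0.56 in all cells. It was 0.56 with genes detected regressed out and 0.47 with values under 10 TPM set to 0. Each lay above all 10000 matched gene triples, whose central 95% ended at 0.16 and 0.17. These values argue against the number of genes detected, and against values under 10 TPM from shared indices, as the whole cause. Larger values from shared indices were not covered. Few values under 1 TPM were there to remove: Hoxa9 was above 0 in 20 cells and at 1 TPM in 18, and Hoxa10 in 31 and 28. The 6 testable genes within 1 Mb of Hoxa9 and Hoxa10 had a mean rho of 0.053 with Hoxa10 (percentile 87.9), between Skap2 at 0.51 and Cbx3 at -0.33. Hoxa3, the only other listed HoxA gene, was at 0 TPM in all 76 cells and was not among the 6. It gave no sign of activity of the region, while Skap2 rose with Hoxa10. Activity of the chromosomal region thus cannot be told apart from that of introduced copies.

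The 6 cells of cluster 4, a group that was recovered only in part under other settings and was lost in a cluster of 47 among cells with at least 3500 genes, carried T lymphoid transcripts. The lower of the medians of Tcf7 and Lck was 27.8% of the highest value of the gene, and the lowest single value was 3.74%. Both lie above the 0.21% of low values that followed a title. That 0.21% came only from values under 10 TPM, so larger shares of a high cell were left out of it. The comparison therefore cannot decide on shared indices among these 76 cells. The highest values of Tcf7 (1687 TPM) and Lck (2345 TPM) lay in the group itself, which was singled out after these genes were seen. The comparison does not cover the cells that held them. Of 9 listed genes of mature T cells, a median of 2 per cell (range 1 to 3) was at 10 TPM or more, and 1 of these genes, Lat, was so in 52 of the 70 other cells; Cd3e, Bcl11b and Cd5 were in 0. The median met the bound set for excluding mature T cells, which was at most 2 in the median cell. Mature T cells in the sort stay open all the same, because single cells reached 3 and failed capture lowers such counts. The cells detected fewer genes than the others by 0.47 SD (-0.47), which does not decide on pairs of cells in a well, and no explanation is put forward.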
